A study of Mus musculus with 2 samples.

How the data were processed

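Total RNA (300 ng per library) came from hippocampus of male 5xFAD/CAST mice, labelled as layer of hippocampus tissue. It was depleted of ribosomal RNA, given ERCC spike-in RNAs and made into strand-specific libraries, per the labels. The 2 libraries are biological replicates 1 and 2 of 1 group, per the labels, which give both the same donor identifier. Each library came with a gene table and a transcript table made from alignments to the transcriptome, and with a transcript table made from the reads and an index without an alignment, on the mm10 assembly with the GENCODE M21 annotation, per the notes deposited with each library. The aligner and the quantifiers are not given in the sources used here. The column set of the alignment-based tables is the one RSEM writes and that of the alignment-free table is the one kallisto writes.

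The deposited expected counts are the authors' estimates of reads per gene or transcript and need not be whole numbers, per the file headers. The deposited TPM values were scaled by the authors for length and depth over all genes, spike-ins and further entries, and the deposited FPKM values are fragments per kilobase scaled by the authors to depth, per the file headers. The deposited percent column of the alignment-based transcript table is the share of a gene's TPM held by each transcript, per the file headers. The estimated counts and TPM of the alignment-free table were deposited per transcript and were summed per gene here. The gene table also gives posterior mean TPM values and, per gene, a coefficient of quartile variation of TPM, which widens for low counts and for reads that several genes share.

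The gene table held 55536 annotated genes, whose identifiers all matched the GENCODE M21 annotation used for names, classes and positions, 96 ERCC spike-ins, 1 phiX entry and 26248 entries named only by a number, which held 6 counts in replicate 1 and 5 in replicate 2. Spike-ins, phiX and numbered entries were left out of tests and gene lists. Totals over the whole gene table were 26128897 and 28689423 expected counts. An expected count of 0 allows up to 3 counts, or 0.115 and 0.105 CPM.

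With 1 group of 2 libraries there was no test between conditions. Detection was counted at TPM of at least 1 in both libraries. Expected counts were rounded for edgeR (version 4.0.16, R version 4.3.3), which gave the common biological coefficient of variation with an intercept-only design on genes passing its expression filter and TMM scaling factors. The log2 ratio of replicate 2 over replicate 1 used TMM-scaled expected counts with a prior count of 0.5 for genes with a mean expected count of at least 20. An exact conditional binomial test on the rounded counts, two-sided with Benjamini-Hochberg adjustment, compared the libraries only. Gene lists, 37 in number, were fixed before the data were examined. A list's median log2 ratio, over at least 4 members with a mean expected count of at least 20, was placed among 10000 random lists of the same size drawn within 20 bins of mean expression. Rows that share a gene symbol were summed for the lists. Python (version 3.11.15) with numpy (2.4.6), pandas (2.3.3) and scipy (1.17.1) was used for the rest and matplotlib (3.10.9) for the plots.

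The steps were checked on simulated counts with the libraries' own means and sizes. Of 200 genes simulated 4-fold apart, 100% were found more than 2-fold apart in the right direction, as were 0.321% of unchanged genes, over 17020 genes. The coefficient of variation came out at 0.0996 for a simulated 0.1 when only unchanged genes entered, and at 0.142 when the changed genes entered too. Of 100 random lists of unchanged genes, 5 lay outside the central 95%.

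Genes were named by a rule fixed before the data were examined. It took the 3 members of each list with the highest mean TPM, where they reached TPM of 1 in both libraries, all members of the APP processing and disease-associated microglia lists, the 10 highest protein-coding nuclear genes, and the 5 protein-coding nuclear genes per direction with the largest ratio among genes more than 2-fold apart and with a mean expected count of at least 100. It also took Xist, the Y-linked genes and the leading transcripts of App, Mapt, Apoe, Bin1, Clu, Camk2a, Gfap, Mbp and Trem2. Some genes that the rule took are not described here. Ratios of the alignment-free to the alignment-based count were examined after the data were seen, for protein-coding genes with at least 500 expected counts. Alternatives covered DESeq2 (version 1.42.0) size factors, library size and spike-in scaling, TPM ratios, count and TPM thresholds, pseudocounts of 1 and 0.1, FPKM, posterior mean TPM, the alignment-free table, other list summaries, other matching of random lists and leaving out each replicate. Leaving out a replicate was not possible for values that need both libraries.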

Results

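Total RNA from the hippocampus (layer of hippocampus tissue, per the labels) of adult male 5xFAD/CAST mice aged 8 to 10 months was sequenced. There were 2 libraries, which the labels call biological replicates 1 and 2 of 1 group. 5xFAD mice carry a human APP transgene with mutations of familial Alzheimer disease, driven by a Thy1 promoter. The libraries held 26128897 (replicate 1) and 28689423 (replicate 2) expected counts, so 1 count was worth 0.0383 and 0.0349 CPM. Mice without the transgene were not analysed here, and no comparison between conditions was made. Gene groups were compared within each library, the libraries with each other, and the deposited quantifications with each other. The labels give both libraries 1 donor identifier, so every SD below measures only the spread between these 2 samples, which may be technical. Every p-value below sets a difference between these 2 libraries against counting error alone, and intervals and floors cover counting error only.

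Neuronal transcripts stood at high levels in both libraries. The synapse list had a median of 230 ± 15.8 TPM (SD, n = 2), with Snap25 at 864 ± 78.9, Syp at 707 ± 48.0 and Vamp2 at 401 ± 25.3 TPM, all proteins of synaptic vesicle release. Markers of excitatory neurons had a median of 121 ± 17.3 TPM and those of inhibitory neurons 27.3 ± 0.714 TPM. The ratio of these medians was 2.15 ± 0.17 on the log2 scale (SD, n = 2), or 4.43-fold, many times its spread. Camk2a, a calcium-dependent kinase of the postsynapse, reached 1270 ± 101 TPM, Hpca 743 ± 148 TPM and Nrgn 531 ± 73.1 TPM. The highest inhibitory markers were Sst, a neuropeptide, at 141 ± 8.76 TPM, and Gad1, which makes GABA, at 130 ± 12.5 TPM.

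Each hippocampal subfield was represented by its own markers. The CA1 list had a median of 31.8 ± 2.48 TPM (SD, n = 2), the dentate granule list 20.9 ± 3.04 TPM, the CA3 list 17.8 ± 2.47 TPM and the CA2 list 7.33 ± 0.407 TPM, with every member at TPM of at least 1 in both libraries. Leading CA1 markers were Lmo4 (90.9 ± 3.30 TPM), Mpped1 (71.1 ± 3.18 TPM) and Wfs1 (60.5 ± 4.43 TPM). In the dentate list, Dock10 reached 36.9 ± 0.912 TPM, the transcription factor Prox1 28.6 ± 3.79 TPM and C1ql2 27.7 ± 4.60 TPM. Cpne4 led the CA3 list at 46.2 ± 12.1 TPM, followed by Trps1 at 20.6 ± 1.27 and Grik4 at 19.9 ± 2.49 TPM. For CA2 the values were 110 ± 16.9 TPM for Pcp4, 41.2 ± 2.82 TPM for Rgs14 and 8.27 ± 1.30 TPM for Amigo2. The CA1 median exceeded the CA3 median by 0.84 ± 0.09 and the dentate median exceeded it by 0.23 ± 0.01 on the log2 scale (SD, n = 2). A list's level depends on the markers chosen for it and is no measure of cell numbers.

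Genes of neuronal activity and of young neurons were low. Immediate early genes had a median of 6.35 ± 0.127 TPM (SD, n = 2), led by Arc at 24.8 ± 8.06, Junb at 24.3 ± 4.17 and Egr1 at 22.6 ± 3.33 TPM. Of the 10 genes of immature neurons and cell division, 4 reached TPM of 1 in both libraries, and their median was 0.78 ± 0.0141 TPM. Calb2 stood at 18.6 ± 1.99, Neurod1 at 8.50 ± 0.368 and Dcx, a microtubule protein of migrating neurons, at 6.37 ± 1.09 TPM.

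Astrocytes and oligodendrocytes had similar medians, at 78.8 ± 0.513 and 77.3 ± 2.02 TPM (SD, n = 2). The glutamate transporters Slc1a2 and Slc1a3 stood at 799 ± 12.5 and 187 ± 2.56 TPM, and Aldoc at 399 ± 28.0 TPM. Myelin genes reached 733 ± 16.5 TPM for Mbp and 178 ± 2.49 TPM for Mobp. Oligodendrocyte precursors were lower, at a median of 8.48 ± 0.209 TPM, with Tnr at 58.2 ± 0.997, Pdgfra at 19.3 ± 1.87 and Gpr17 at 10.3 ± 0.240 TPM. The median of mature oligodendrocytes was 9.12 times that of precursors. Within the reactive astrocyte list, whose median was 6.58 ± 0.460 TPM, Gfap, the intermediate filament of astrocytes, reached 837 ± 22.6 TPM, the complement gene C4b 149 ± 0.516 TPM and the protease inhibitor Serpina3n 75.0 ± 0.997 TPM.

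Disease-associated and homeostatic microglial markers were present at comparable levels. The disease-associated list, which holds genes known to be induced in microglia around amyloid plaques, had a median of 32.5 ± 2.17 TPM, and the homeostatic list 29.7 ± 0.647 TPM (SD, n = 2). All 16 and all 12 members reached TPM of 1 in both libraries. Apoe, a lipid carrier also made by astrocytes, stood at 1729 ± 88.0 TPM and the lysosomal protease Ctsd at 657 ± 10.7 TPM. Next came the signalling adaptor Tyrobp at 199 ± 7.93 TPM, Lyz2 at 106 ± 8.39, Cd9 at 85.7 ± 3.27, the lipid-sensing receptor Trem2 at 79.8 ± 0.255 and Cst7 at 63.1 ± 2.17 TPM. Levels between 17 and 33 TPM were found for Axl (32.8 ± 1.22), Lpl (32.1 ± 3.13), Csf1 (23.9 ± 0.665), Ccl6 (22.8 ± 0.354), Gpnmb (17.9 ± 1.74) and Itgax (17.1 ± 0.658). Clec7a stood at 11.1 ± 1.14 TPM, Ccl3 at 8.51 ± 1.19 TPM, and Spp1, or osteopontin, varied most, at 12.2 TPM in replicate 1 and 5.79 TPM in replicate 2. Homeostatic markers included the receptor Csf1r at 103 ± 3.32 TPM and the fractalkine receptor Cx3cr1 at 48.0 ± 1.98 TPM.

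The log2 ratio of the disease-associated over the homeostatic median was 0.04 in replicate 1 and 0.22 in replicate 2, a mean of 0.13 ± 0.13 (SD, n = 2), about the size of the spread between the libraries. In the alignment-free table it was 0.16 ± 0.02. The direction depended on the summary: without Apoe and Ctsd, which other cells also express, the ratio was -0.09 ± 0.08, and the mean of log2(TPM + 1) over members gave 0.63 ± 0.01. Complement genes had a median of 11.4 ± 0.177 TPM, and besides C4b the C1q chains C1qa (108 ± 0.311 TPM) and C1qb (103 ± 0.997 TPM) were the highest. The interferon response list was low, at a median of 3.0 ± 0.117 TPM, with Ifitm3 at 14.1 ± 1.05 and Ifit3 at 8.10 ± 1.43 TPM.

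Markers of vascular and border cells were read in both libraries. Endothelial markers had a median of 11.8 ± 0.75 TPM, mural markers 6.89 ± 1.73, meningeal fibroblast markers 5.65 ± 1.97, ependymal markers 1.56 ± 0.364 and border macrophage markers 1.09 ± 0.0141 TPM (SD, n = 2). Examples were Ly6c1 (26.1 ± 4.14), Slco1a4 (20.3 ± 2.38) and Itm2a (17.6 ± 0.361 TPM) for endothelium, Vtn (37.3 ± 5.76), Rgs5 (22.5 ± 2.02) and Acta2 (10.8 ± 2.36 TPM) for mural cells and Mrc1 (1.73 ± 0.389), F13a1 (1.41 ± 0.0849) and Pf4 (1.23 ± 0.00707 TPM) for border macrophages. Ciliated ependyma was represented by Rarres2 (11.6 ± 0.382), Ccdc153 (4.05 ± 0.7) and Foxj1 (3.62 ± 0.502 TPM). The red blood cell list, which holds 4 globin genes and the haem synthesis gene Alas2, had a median of 64.2 ± 7.89 TPM (32.7 TPM in the alignment-free table), with Hbb-bs at 80.8 ± 3.88 TPM, but Hba-a1 (77.8 ± 1.61) and Hba-a2 (64.2 ± 7.89 TPM) are near-identical copies whose split of reads is uncertain. None of 10 T cell genes reached TPM of 1 in both libraries, and their median was 0.122 ± 0.0106 TPM. It was low but above that of 16 genes of other organs used as the background, 0.04 ± 0.0354 TPM. The T cell medians were 0.13 TPM in replicate 1 and 0.115 TPM in replicate 2, against background medians of 0.065 and 0.015 TPM. In the background list 1 gene passed TPM of 1, the muscle actin Acta1 at 2.62 ± 0.120 TPM. A gene with 0 counts could still have stood at up to 0.115 CPM in replicate 1 and 0.105 in replicate 2.

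Markers of tissue that borders the hippocampus were also read. The cortex list had a median of 12.6 ± 0.166 TPM (Tshz2 30.8 ± 3.01, Cux2 20.1 ± 2.56, Tle4 17.9 ± 1.36 TPM) and the thalamus list 6.82 ± 0.163 TPM (Prkcd 18.2 ± 2.41, Ntng1 16.7 ± 2.10, Slc17a6 10.2 ± 4.81 TPM; SD, n = 2). The striatum list, at 7.38 ± 5.72 TPM, and the choroid plexus list, at 3.72 ± 3.90 TPM, had SDs near their means, since the libraries differed in them.

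**Figure D1:**
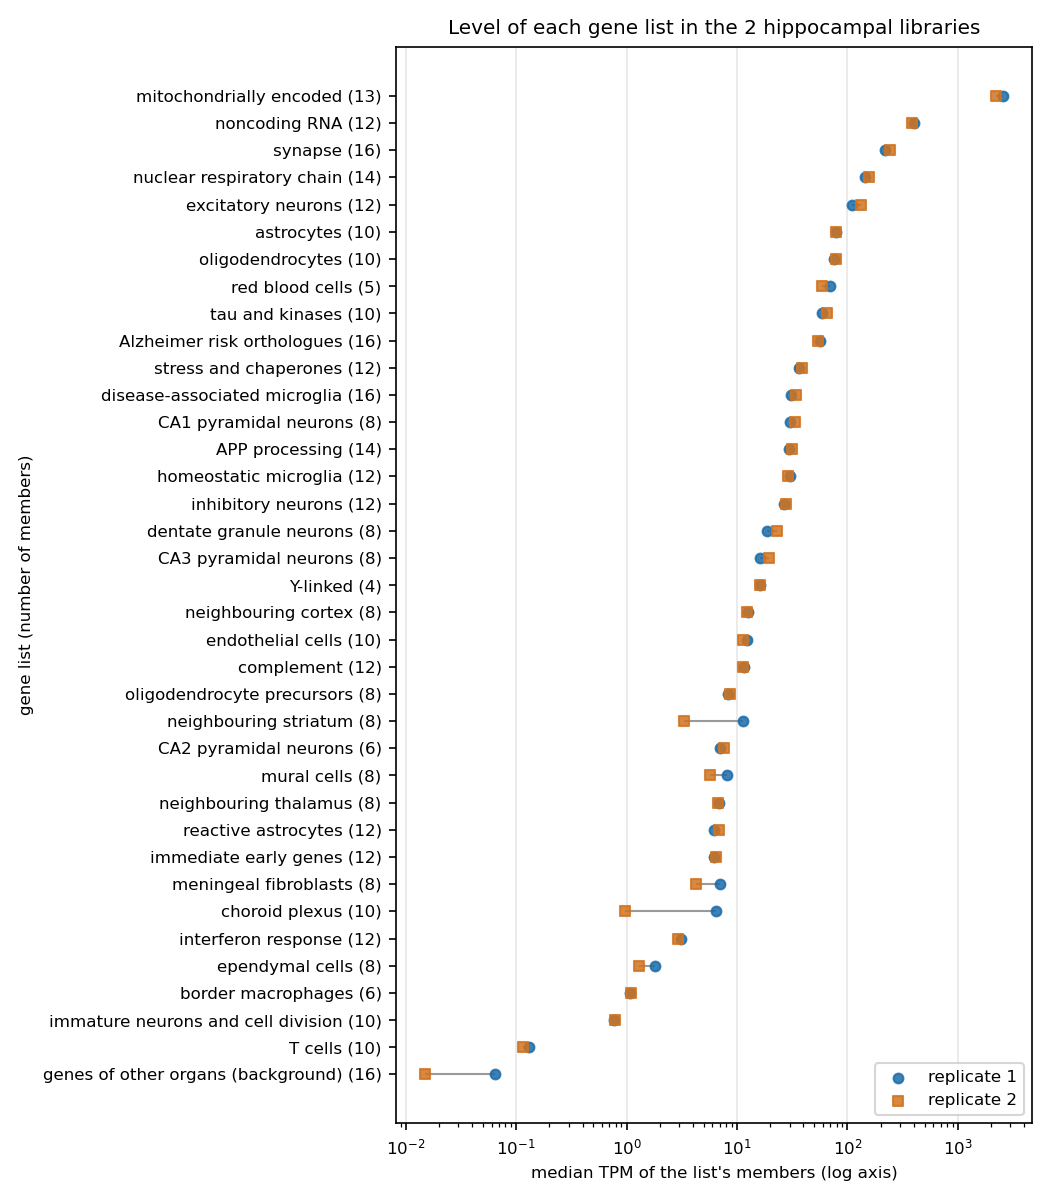
Median TPM (log axis) of each of the 37 gene lists in replicate 1 (circles) and replicate 2 (squares), joined by a line, with the number of members in brackets. The points of most lists lie together, while the striatum list spans 3.34 to 11.4 TPM and the choroid plexus list 0.96 to 6.48 TPM.

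The genes of APP processing had a median of 30.5 ± 1.65 TPM (SD, n = 2). App (chromosome 16, 84949685 to 85173766 in mm10) stood at 522 ± 20.4 TPM, beside its paralogs Aplp1 at 526 ± 18.9 and Aplp2 at 204 ± 2.15 TPM. Gamma-secretase subunits included Psen2 at 11.8 ± 0.417, Psenen at 37.8 ± 0.75, Aph1a at 32.5 ± 1.36, Ncstn at 30.8 ± 0.792 and Aph1b at 9.76 ± 0.679 TPM. The beta-secretase Bace1 was at 32.8 ± 5.08 TPM against 2.67 ± 0.410 TPM for Bace2, the alpha-secretase Adam10 at 29.8 ± 2.95 TPM, and the amyloid-degrading enzymes Ide and Mme at 17.8 ± 1.32 and 1.20 ± 0.573 TPM. These tables count reads on mouse genes, and transgene sequences had no entry of their own in them.

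Mouse orthologues of Alzheimer risk genes had a median of 55.3 ± 1.26 TPM (SD, n = 2). After Apoe, the highest were Clu, a secreted chaperone, at 644 ± 21.3 TPM and the kinase Ptk2b at 291 ± 43.9 TPM. Tau and its kinases had a median of 62.2 ± 4.13 TPM, with the microtubule proteins Map2 and Mapt at 449 ± 6.82 and 140 ± 8.65 TPM and the kinase Gsk3a at 86.8 ± 2.37 TPM. Chaperone and stress genes had a median of 37.9 ± 1.77 TPM, and Hspa8 (712 ± 19.7), Hsp90aa1 (395 ± 53.0) and Hsph1 (117 ± 4.65 TPM) led them. Nuclear genes of the respiratory chain had a median of 151 ± 7.96 TPM, with Atp5b at 688 ± 7.47, Cox4i1 at 467 ± 13.8 and Cox6a1 at 331 ± 12.8 TPM.

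Thy1, a neuronal surface protein (chromosome 9, 44043384 to 44048579), was the highest protein-coding nuclear gene by gene-level TPM, at 2364 ± 312 TPM (SD, n = 2). Its coding transcript Thy1-201 held 983 TPM of this in replicate 1 and 1172 TPM in replicate 2, and whether transgene sequence adds to Thy1 reads was not tested. Thy1 was followed by Cst3 (1876 ± 38.1), Apoe, Fth1 (1598 ± 84.5), Eef1a1 (1558 ± 7.56), Actb (1409 ± 109), Camk2a, Cpe (1175 ± 59.1), Aldoa (1076 ± 135) and Gapdh (1065 ± 70.9 TPM). Fth1, Eef1a1, Actb, Gapdh and Aldoa have processed copies in the genome that can take or give reads.

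The leading transcript of each gene described here was the same in the alignment-based and the alignment-free table in both libraries, while its share differed. App-201 held 88.3 ± 1.07% of App TPM in the alignment-based and 83.2 ± 2.37% in the alignment-free table (SD, n = 2), and Gfap-201 held 93.7 ± 0.232% and 89.2 ± 0.239%. Clu-201 (97.4 ± 0.00681% and 77.2 ± 0.383%), Apoe-209 (86.2 ± 1.69% and 52.7 ± 1.2%) and Mbp-211 (72.1 ± 1.05% and 43.8 ± 1.87%) held less in the alignment-free table. For Mapt-204 the shares were 64.1 ± 1.16% and 62.0 ± 0.780%, for Bin1-201 49.2 ± 2.39% and 44.4 ± 2.40%, for Camk2a-203 60.4 ± 0.290% and 50.2 ± 1.70%, and for Trem2-201 78.2 ± 3.64% and 81.1 ± 3.94%. Over genes with several transcripts and a TPM of at least 10, 81.0 ± 0.617% (SD, n = 2) had the same leading transcript in both tables, 6505 of 8074 genes in replicate 1 and 6586 of 8087 in replicate 2. Across transcripts at TPM of at least 1 in either table, which are not independent replicates, Spearman's rho was 0.612 in replicate 1 and 0.616 in replicate 2.

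App had far more reads in the alignment-free than in the alignment-based quantification. The alignment-free count of App was 2.26 ± 0.114 times its alignment-based count (SD, n = 2), 62922 against 28882 in replicate 1 and 76307 against 32606 in replicate 2. The ratios of Aplp1 (1.1 ± 0.000133), Aplp2 (1.11 ± 0.00118), Bace1 (1.13 ± 0.00426), Adam10 (1.16 ± 0.00655) and Ncstn (1.18 ± 0.0131) stayed near the median of protein-coding genes, 1.14 in either library. Thy1, whose promoter drives the transgene, had a ratio of 1.23 ± 0.00106, at percentiles of 93.8 in replicate 1 and 94.6 in replicate 2. Among protein-coding genes with at least 500 counts, App ranked 12 of 7530 in replicate 1 and 9 of 7839 in replicate 2.

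**Figure D2:**
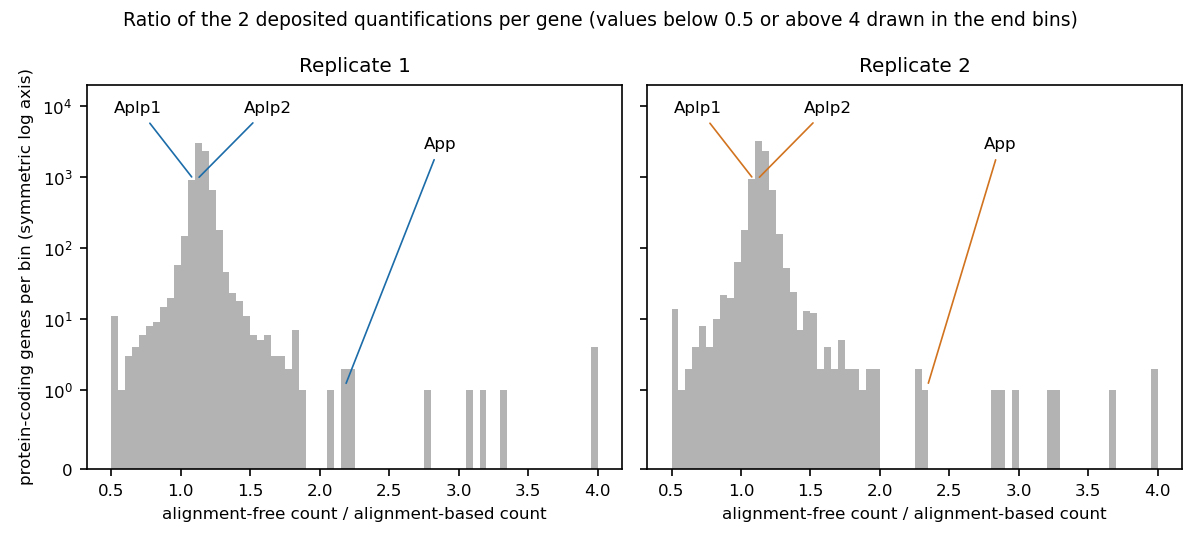
Number of protein-coding genes with at least 500 expected counts (symmetric log axis) by the ratio of their alignment-free to their alignment-based count, per library, with App, Aplp1 and Aplp2 marked by lines. App (2.18 and 2.34) lies far above the medians of 1.14, and Aplp1 and Aplp2 lie just below them.

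Most reads came from protein-coding nuclear genes, which held 78.5 ± 0.824% of the expected counts (SD, n = 2) but 45.2 ± 1.23% of TPM. The mitochondrial genome held 9.11 ± 0.456% of counts, long noncoding and unprocessed loci 5.88 ± 0.0847%, small noncoding RNAs 4.74 ± 0.165%, pseudogenes 1.28 ± 0.0522% and nuclear ribosomal RNA 0.000236 ± 0.0000672%. Small noncoding RNAs held 35.1 ± 0.669% of TPM because their short length raises it. Rn7sk, the RNA of the 7SK particle, stood at 66708 ± 334 TPM, Rpph1 at 6449 ± 45.6 and Malat1 at 5822 ± 203 TPM, in a noncoding RNA list with a median of 392 ± 15.1 TPM. The mitochondrially encoded genes had a median of 2388 ± 260 TPM, with mt-Co1 at 6880 ± 508, mt-Co3 at 4393 ± 510 and mt-Cytb at 3839 ± 305 TPM. Nuclear copies of mitochondrial DNA may share reads with some of these, which was not tested. The levels of these genes, and the shares of counts on the mitochondrial genome and on pseudogenes, are therefore uncertain. Of 343389 and 355867 pseudogene counts in replicates 1 and 2, Gm28661 on chromosome 1 held 91767 and 88032.

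The Y-linked genes Eif2s3y (29.7 ± 1.02 TPM), Ddx3y (21.3 ± 0.368), Uty (10.9 ± 0.262) and Kdm5d (9.03 ± 1.51) were read in both libraries, labelled as male, with a list median of 16.1 ± 0.0530 TPM. Xist, the RNA of the inactive X chromosome, stood at 0.11 and 0.09 TPM. The added ERCC spike-in RNAs took 0.494 ± 0.0660% of counts (SD, n = 2). Of the 96 spike-ins, 61 were read in both libraries, and across these Pearson's r of log2 TPM was 0.986.

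Most genes differed little in size between the libraries, while markers of a few tissues were far apart. Of 55536 annotated genes, 15710 reached TPM of 1 in both libraries, 13294 of them protein coding, and 874 did so in replicate 1 only and 585 in replicate 2 only. Across 17169 genes at TPM of 1 in either library, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.977 and Spearman's rho 0.979. The common biological coefficient of variation from edgeR was 0.0886 over 18082 genes. Of 16971 genes with a mean expected count of at least 20, the median absolute log2 ratio was 0.12 and 340 were more than 2-fold apart, 261 higher in replicate 1 and 79 higher in replicate 2. By the exact conditional binomial test, two-sided with Benjamini-Hochberg adjustment, 314 of the 340 differed beyond counting error at an adjusted p under 0.05, a test that compares these libraries and no conditions. The test takes the expected counts as given and leaves out uncertainty in assigning shared reads, so some of the 314 may differ only in that assignment. At any fold, 3127 of the 16971 genes (18.4%) had an adjusted p under 0.05 in that exact test. Scaled by the spike-ins instead, the median log2 ratio of all genes was 0.27, and 326 genes were more than 2-fold apart, 146 higher in replicate 1 and 180 in replicate 2.

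Choroid plexus and striatal genes were the groups furthest apart, and all tested members of both were higher in replicate 1. The choroid plexus list had a median log2 ratio of replicate 2 over replicate 1 of -2.71 (10 of 10 members lower in replicate 2), and the striatum list -1.65 (8 of 8), each below all of 10000 expression-matched random lists. Ttr, the thyroid hormone carrier secreted by the choroid plexus (chromosome 18, 20665280 to 20674321), stood at 1151 TPM in replicate 1 and 174 TPM in replicate 2, Kl at 13.4 and 4.62 TPM and Folr1 at 10.7 and 1.43 TPM. Ppp1r1b, or DARPP-32, stood at 68.4 and 24.9 TPM, Pde10a at 36.6 and 23.5 TPM and Rgs9 at 17.7 and 7.21 TPM. Meningeal fibroblast genes followed at -0.72 (8 of 8 members), with Igf2 at 70.3 and 23.4 TPM and Slc6a13 at 10.8 and 4.75 TPM, while Dcn was alike at 26.5 and 26.9 TPM.

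Among protein-coding nuclear genes with a mean expected count of at least 100, the largest ratios towards replicate 1 were those of Avp, Igfn1, Mfrp and Adora2a. Avp, which encodes vasopressin (chromosome 2, 130580620 to 130582554), had 257 expected counts in replicate 1 and 5 in replicate 2, a log2 ratio of -5.67 with an adjusted p of 1.27e-71 in the exact binomial test. The striatal receptor gene Adora2a (chromosome 10, 75316877 to 75334784) had a log2 ratio of -3.34 (adjusted p = 1.17e-49, exact binomial test). Igfn1 (log2 ratio -3.48) and Mfrp (-3.35) had 209 and 291 expected counts in replicate 1 and 20 and 30.8 in replicate 2. In the other direction the ratios were smaller: 1.63 for 1700047I17Rik2, 1.58 for Gm20517, 1.52 for Gm5796, 1.23 for Fam220a on chromosome 5 and 1.15 for Gm20458. All 5 had fractional counts, as had Avp and Mfrp. Another gene entry named Fam220a spans nearly the same stretch of the same strand and had a log2 ratio of -1.88. Expected counts in replicates 1 and 2 were 311 and 797 for the first entry and 343 and 102 for the other. Neither ratio therefore stands for the locus. In the library with more counts, the deposited TPM quartile variation of these 5 was 0.0875 to 0.298 and that of Avp, Igfn1, Mfrp and Adora2a 0.0419 to 0.0787, while in the library with fewer counts it was above 0.1 for all of them, so the size of each ratio is uncertain.

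Lists of excitatory, CA1, CA3 and dentate neurons and of synapse and immediate early genes lay slightly higher in replicate 2. With spike-in scaling their medians were 0.38 to 0.58, but the median of all genes also rose, to 0.27. These lists therefore stood no further from other genes under that scaling. Median log2 ratios were 0.31 for dentate granule neurons (6 of 8 members higher in replicate 2), 0.26 for excitatory neurons (10 of 12), 0.23 for CA3 (7 of 8), 0.16 for immediate early genes (9 of 12), 0.15 for the synapse list (16 of 16) and 0.12 for CA1 (7 of 8), at percentiles from 98.6 to 100 among the random lists. Arc stood at 19.1 TPM in replicate 1 and 30.5 TPM in replicate 2. In total 18 of the 34 lists with at least 4 tested members lay outside the central 95% of their random lists, where 1.7 would by chance, 12 towards replicate 1 and 6 towards replicate 2.

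The remaining 9 lists lay slightly higher in replicate 1 with TMM scaling, but not with spike-in scaling. Their medians were -0.23 for immature neurons and cell division (percentile 1.85), -0.22 for cortex (0.1) and endothelium (0.07), -0.21 for mural cells (0.71), -0.18 for mitochondrially encoded genes (0), -0.10 for homeostatic microglia (0.09), -0.08 for astrocytes (0.29), -0.08 for noncoding RNA (0.02) and -0.08 for disease-associated microglia (0.45). Scaled by the spike-ins, these 9 medians turned positive while all 18 lists stayed outside the central 95%, so only their place relative to other genes is shown. On the TPM ratio CA1, immature neurons and astrocytes moved inside the range, at percentiles of 89.0, 4.80 and 3.64, and the Alzheimer risk orthologues moved outside it, at 2.06. Immature neurons also moved inside at a mean count of at least 5 (6.06) and with random lists matched on gene length (3.59), and lay outside in 5 of 8 alternatives.

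The other 16 lists lay inside the range. Inhibitory neurons (0.00), oligodendrocytes (-0.03), oligodendrocyte precursors (-0.00), tau and kinases (0.02), red blood cells (0.02), Alzheimer risk orthologues (-0.03), Y-linked genes (-0.04), APP processing (0.05), thalamus (0.05), reactive astrocytes (-0.05), complement (-0.05), stress and chaperones (0.06) and the nuclear respiratory chain (0.06) had median log2 ratios close to 0. CA2 was at 0.11, the interferon response at -0.21 and ependymal cells at -0.26, where the random lists of their expression also spread wider. For 8 of the 34 lists, disease-associated microglia and oligodendrocytes among them, the median TPM and the median log2 ratio differed in sign.

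**Figure D3:**
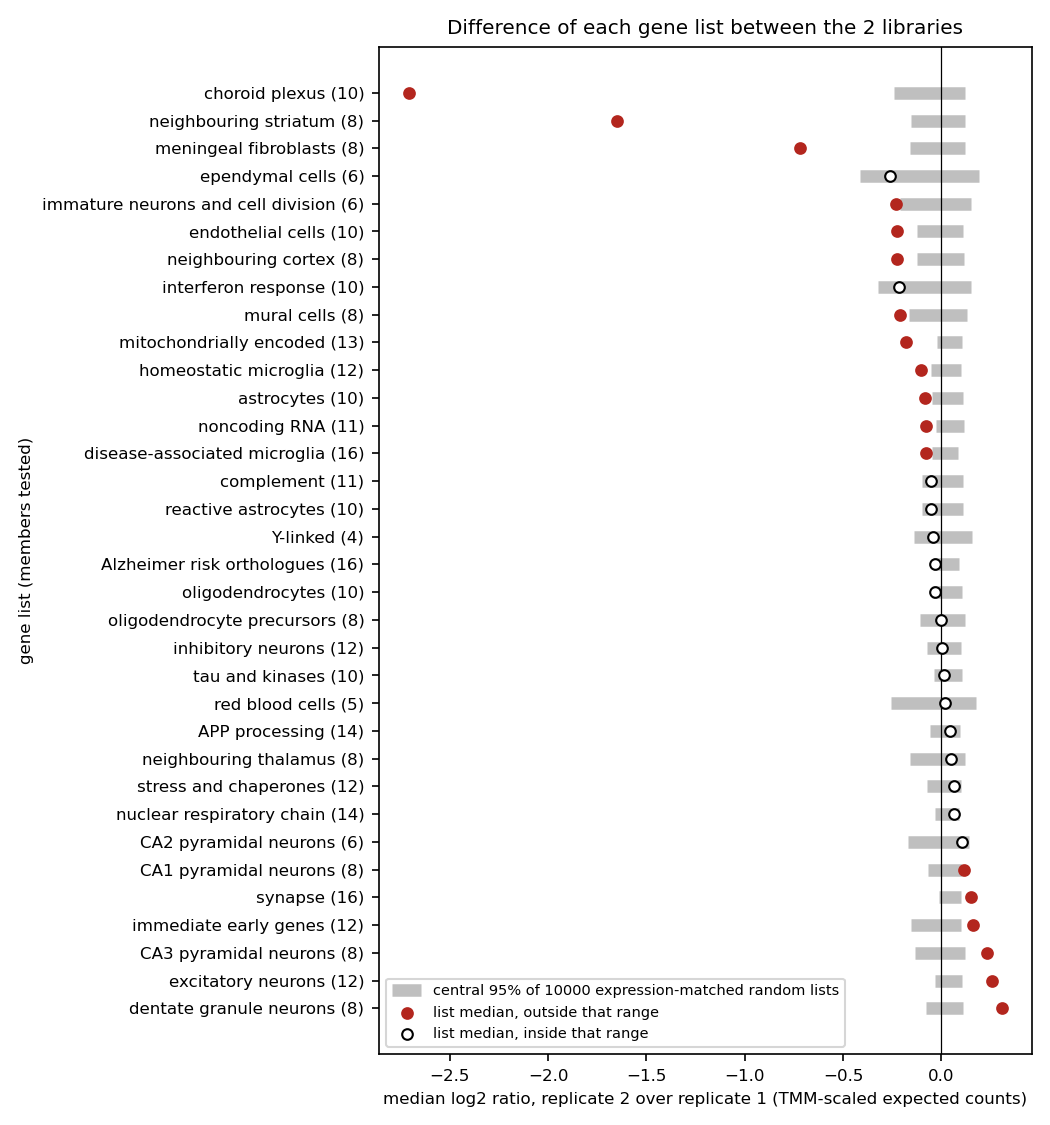
Median log2 ratio (replicate 2 over replicate 1, TMM-scaled expected counts) of the 34 gene lists with at least 4 tested members. Grey bars span the central 95% of 10000 expression-matched random lists, filled points lie outside that range and open points inside it, with choroid plexus at -2.71 and dentate granule neurons at 0.31 as the extremes.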

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

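Of the tests in this part, those of a scaling difference, of count-matched genes and of whole-number counts were chosen after the result was seen, and the others after the pattern but before the tested values were seen.

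Reads on the phiX entry, the sequencing control genome, lay outside the main measurement: 211 expected counts in replicate 1 and 197 in replicate 2, above the 3 counts that an observed 0 allows. No control samples were analysed here to set a background for them.

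Choroid plexus and striatal markers were higher in replicate 1, at median log2 ratios of -2.71 and -1.65. A scaling difference adds 1 constant to every gene and leaves no gap between a list and all genes, so as the whole cause it is argued against by the gap itself, -1.65 for the nearer of the lists. Tissue next to the hippocampus taken along in replicate 1 remains a candidate explanation for these 2 lists. Not every bordering tissue differed alike: the cortex list was at -0.22 (percentile 0.1) and the thalamus list at 0.05 (percentile 81.3). Avp, at a log2 ratio of -5.67, is a marker in neither the choroid plexus nor the striatum list, and whether it shares their cause was not tested. Further lists written before their values were looked at lay at -1.54 for choroid plexus (8 of 8 members lower in replicate 2, led by Enpp2 at 258 and 99.7 TPM) and -0.59 for striatum (9 of 10, all but Cnr1), both at percentile 0 of 10000 random lists, although 8 of the 12 genes of that striatum list also reached TPM of 1 in replicate 2. A difference between the animals was not tested, and no biological explanation could be tested within 1 group.

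App had 2.26 ± 0.114 times as many reads in the alignment-free as in the alignment-based table (SD, n = 2). Among protein-coding genes with at least as many annotated transcripts (1270 in replicate 1 and 1296 in replicate 2), the lower percentile of App over the libraries was 99.8. App was picked for its rank, 12 of 7530 and 9 of 7839 genes, which already fixed a percentile above 99 in these subsets. Its place there therefore cannot decide whether a difference between the quantifications grows with the number of annotated transcripts. Reads of the human APP transgene, similar in sequence to the mouse gene and counted only without a full alignment, may add to the alignment-free count and stay open as an explanation. The percentile of App in replicate 2, 99.9, repeats that of replicate 1 and would do so under any cause set by sequence or software, so it does not tell such causes apart. Neither strain variants nor libraries without the transgene were tested.

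With TMM scaling, 79 genes were more than 2-fold apart and higher in replicate 2, against 261 higher in replicate 1, a balance that turned with spike-in scaling (180 against 146), whose genes were not examined in this way. Reads shared between near-identical copies, or between overlapping entries such as those of Fam220a, may account for these 79. Of them, 98.7% (78 genes) had a deposited TPM quartile variation above the 90th percentile of all tested genes, where genes of matched counts gave 47.5%. Of these genes, 67.1% had counts that were not whole, the mark of a read split between entries, against 19.2% of count-matched genes. Among the genes higher in replicate 1 the same shares were 66.3% (count-matched 35.3%) and 21.1% (18.8%). The genes with whole counts remain unexplained, and no biological explanation was tested.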

How the results depend on the processing

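Alternatives chosen after the data were seen are the protein-coding and quartile-variation settings of the 2-fold genes, the library-size and spike-in scaling of the lists and the alignment-free count of detected genes. The 340 genes more than 2-fold apart became 1326 with a mean count of at least 5 (898 higher in replicate 1) and 82 at a mean count of at least 100 (72 higher in replicate 1), by construction from other numbers of genes with low counts. With a quartile variation under 0.1 they became 48 (47 higher in replicate 1). With spike-in scaling they were 326, and the balance turned to 146 higher in replicate 1 and 180 in replicate 2. The other settings gave 227 to 349 genes, with more of them higher in replicate 1. Pearson's r of 0.977 became 0.938 with a pseudocount of 0.1, 0.992 with no filter on low values, 0.969 at TPM of at least 5 and 0.994 on TMM-scaled CPM. The coefficient of variation of 0.0886 became 0.0965 with no filter, 0.0833 at a mean count of at least 100 and 0.0835 for protein-coding nuclear genes. The disease-associated over homeostatic ratio of 0.13 turned to -0.0916 without Apoe and Ctsd and became 0.63 with the mean of log2(TPM + 1) or of log2(TPM + 0.1), and leaving out a replicate gave 0.04 to 0.22. On TPM the share of protein-coding nuclear genes was 45.2% in place of 78.5% (77.9% to 79.1% with a replicate left out) and that of spike-ins 0.931% in place of 0.494%. Spearman's rho between the transcript tables became 0.667 for transcripts at TPM of at least 0.1 and 0.573 at TPM of at least 5, and the percent of genes with the same leading transcript 79.2 for genes at TPM of at least 1. Except where construction is named, the cause was not tested. The counts of genes detected (11114 to 19783), of lists outside the central 95% (16 to 18 against 18) and of lists with a median TPM of at least 10 (22 to 30 against 22) stayed within 1.5 times the main counts in all settings run. Rescaling TPM to nuclear protein-coding genes moved all 37 list medians by more than their SD, and the alignment-free table moved 18 of 37. With 2 replicates, leaving 1 out moves a mean by less than 1 SD by construction and tests nothing.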

Other observations

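Groups of genes listed after the data were seen add to the picture of these libraries. The neuropeptide list, written after Avp, Penk and Tac1 had been seen to differ and so no test of that difference, had a median log2 ratio of replicate 2 over replicate 1 of -1.06 over 14 members, 10 of them higher in replicate 1. Of 4 members picked after their values were seen, Avp stood at 29.7 TPM in replicate 1 and 0.54 TPM in replicate 2, Pmch (melanin-concentrating hormone) at 9.09 and 0.16 TPM, from 107 and 2 counts, and Hcrt (orexin) and Oxt (oxytocin), too low to be tested, had 21 and 15 counts against 0. In all, 10 of the 16 members reached TPM of 1 in both libraries. The opioid precursors Penk (53.7 and 15.5 TPM) and Pdyn (9.53 and 4.65 TPM) and the tachykinin gene Tac1 (15.1 and 2.73 TPM) were also higher in replicate 1. Peptides of cortical and hippocampal interneurons were read in both libraries, with Cck at 226 ± 30.0, Sst at 141 ± 8.76, Npy at 31.7 ± 2.41 and Vip at 5.83 ± 0.983 TPM (SD, n = 2).

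Antigen presentation genes had a median of 14 ± 2.54 TPM (SD, n = 2). The class I genes stood at 175 ± 1.59 TPM for B2m, 48.6 ± 2.93 TPM for H2-D1 and 45.3 ± 4.94 TPM for H2-K1. Of the class II genes, Cd74 stood at 71.2 and 49.3 TPM, H2-Aa at 22.5 and 13.3 TPM and H2-Eb1 at 14.6 and 11.2 TPM in replicate 1 and replicate 2, and no test set the classes apart. The list's median log2 ratio with TMM scaling was -0.27, at percentile 0.02, with 9 of 12 members higher in replicate 1. Lysosomal genes had a median of 86.5 ± 3.36 TPM and a median log2 ratio of -0.08 (percentile 0.01), led by Ctsd, Ctsb at 302 ± 8.53 and Ctss at 233 ± 5.30 TPM. With spike-in scaling the median log2 ratio of all genes was 0.27, so only the place of the antigen presentation and lysosomal lists relative to other genes is shown.

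More than 50% of Thy1 TPM lay on a short transcript without a coding sequence, a feature chosen after its values were seen. Thy1-203 (chromosome 9, 44047922 to 44048574, 449 nucleotides in 2 exons) lies within the 3' UTR of Thy1-201, which spans 44047449 to 44048579 in exon 4. It held 53.5 ± 0.401% of Thy1 TPM in the alignment-based and 50.8 ± 0.935% in the alignment-free table (SD, n = 2), from 7228 and 9408 expected counts, against 29153 and 37142 on Thy1-201.

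Of the mitochondrial genes, mt-Co2, also chosen after its values were seen, stood at 175 TPM in replicate 1 and 283 TPM in replicate 2, far under mt-Co1, and was the only one of the 13 higher in replicate 2 (log2 ratio 0.66). The alignment-free table gave it 873 and 939 TPM. Among pseudogenes in a nuclear insert on chromosome 1, Gm28661 (24614885 to 24615565) took 8706 and 7820 TPM in the alignment-based and 6676 and 6365 TPM in the alignment-free table. Its neighbour Gm10925 (24613974 to 24614651) took 6063 and 5701 TPM in the alignment-based and 1570 and 2042 TPM in the alignment-free table. Which mitochondrial gene each resembles was not tested.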
